A study of Drosophila melanogaster with 15 samples.

How the data were processed

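Expression was measured on 15 Affymetrix 3' expression arrays of Drosophila melanogaster, 1 array per pool of whole bodies of adult males. There were 4 arrays of untreated control flies, 4 of untreated flies of 4 Dsup lines, 3 of control flies after ionizing radiation and 4 of the same Dsup lines after radiation. Per the labels' protocols, the flies were 3 days old, 25 flies made a sample, the dose was 1000 Gy, and biotin-labelled antisense RNA was made from total RNA with a 3' labelling kit. The time between irradiation and RNA isolation, the summary of probes into probe sets and the normalization are not given in the sources used here.

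The deposited table holds log2 probe set levels, read as such from their range and spread, for 18952 probe sets. No raw intensities or detection calls were used here, and the number of arrays, not a read depth, limits the precision. The deposited values looked as if each group had been normalized on its own. The means of the arrays of a group lay within 0.0217 of each other, while the group means spanned 0.830. Pairs of irradiated control arrays shared between 6814 and 7744 identical values of 18952, against at most 209 in any other pair. In simulated probe data, median polish over 3 arrays gave identical summaries in 20.9% of pairs and over 4 arrays in 0%. The observed shares were 36.0% to 40.9% in pairs of irradiated controls and 0.106% to 1.10% in pairs within the other groups. The simulation, run at 1 setting of noise, thus did not reach the observed shares and does not settle how they arose. An offset that a separate normalization gives to 1 probe set in a whole group cannot be separated from a difference between groups by any rescaling of the deposited table.

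The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The deposited log2 values were then analysed as planned, and so were values after quantile normalization of all 15 arrays, after centring each array on its median and after centring it on the cytosolic ribosomal protein genes. Once the offset between groups had been seen, the quantile-normalized values were taken for the description of genes and gene groups, with the counts from the deposited and the centred values beside them. All log2 changes, levels and standard errors in the results are from quantile-normalized values unless another scaling is named.

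The 183 Affymetrix control probe sets were left out, which left 18769 tested. Of these, 13647 carried exactly 1 gene symbol, 402 carried several and 4720 none. A gene was represented by its probe set with the highest mean, which gave 11982 genes. No symbol needed updating. The genome build behind the probe sets is not named in the annotation used here, so no coordinates are printed.

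Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 4 groups was fitted to all 15 arrays, followed by plain empirical Bayes moderation and 5 contrasts. These were Dsup lines against control in untreated flies, the same after radiation, irradiated against untreated flies in the control, the same in the Dsup lines, and the interaction, which is the radiation response of Dsup lines minus that of control flies. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets. A probe set was called at an adjusted p below 0.05, and the number called with a change of at least 2-fold is given beside it. These p-values measure the spread between these samples, pooled over the 4 groups. As deposited, pairs of irradiated controls share between 6814 and 7744 identical values of 18952, which by themselves lower that pooled spread. The standard errors and p-values may therefore be too small, above all where irradiated controls are compared. The size of this effect was not computed. The labels give the control arrays as biological replicates and the Dsup arrays of a treatment as different transgenic lines, and name no separate control stocks. A difference in genetic background between controls and Dsup lines therefore cannot be told apart from the transgene. The p-values do not measure spread between control stocks.

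Of 31 gene lists, 30 had at least 4 measured members and were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. The histone list had too few measured members. Members were counted from the calls over all genes and from p-values adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a set's genes move one way on balance, were run beside it. After quantile normalization, camera with an estimated correlation called 0 lists in each of the 5 comparisons; at an unadjusted p below 0.05 it gave 1, 1, 3, 0 and 3 lists, and fry called 5, 5, 18, 4 and 5, in the order of the contrasts above.

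Genes were named by a fixed rule. It takes the 8 genes with the largest rise and the 8 with the largest fall (5 and 5 for the interaction) among called genes whose groups' arrays did not overlap and whose brighter group mean lay at or above the median level of all probe sets; for the interaction, overlap of arrays was not asked. It adds 3 members of each called list, those with the smallest p, and the genes skl, Corp, p53 and Yp1. The rule was applied to the deposited values as written. It was applied a second time to the quantile-normalized values, an addition made after the data were seen. The genes w, rpr, hid and Xrp1, also on that fixed list of names, had no probe set of their own symbol and were not analysed here. Hsp70, on it too, had only probe sets that match several genes, and these are named as such.

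Samples were grouped by their labels. Dsup line numbers occur in untreated and irradiated flies, but residuals of arrays with the same line number correlated with r of only -0.01, 0.11, -0.10 and -0.18, so the lines were not paired. A block for the Dsup line was run as an alternative. Control replicate numbers were not treated as pairs.

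The labels name no array processing batch, so it was inferred from the spike-ins. The level of the poly-A spike-ins relative to the hybridization spike-ins was cut at its widest gap, at -3.91. The arrays beside the gap were untreated control 3 (-3.66) and irradiated control 3 (-4.15). This inferred split gave a first batch of 7 (untreated controls 1 to 3, irradiated controls 1 and 2, line 1 untreated and irradiated) and a second of 8 (the rest). Both hold arrays of all 4 groups, and values within each batch are printed beside the pooled ones. A value within a batch often rests on 1 array in an arm, which is assumed to vary like the others. The irradiated controls of both batches share identical values, and an offset from separate normalization of a group would be common to both batches. Agreement between the batches is therefore no independent replication.

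On simulated data, with 200 of 18769 probe sets changed, the fit recovered 97.0% of 2-fold changes in untreated Dsup lines, 97.0% in irradiated Dsup lines against control, 97.0% for radiation in control flies, 95.5% for radiation in Dsup lines and 80.6% for the interaction. At 1.5-fold the shares were 77.6%, 64.2%, 65.7%, 74.6% and 31.3%, and at 3-fold 98.5%, 97.0%, 98.5%, 98.5% and 97.0%. The false calls numbered 9, 12, 7, 10 and 6. The simulated arrays had independent normal noise and held no group offset, batch, outlying array or shared identical values. These shares and false calls therefore do not cover such features of the data.

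The other settings fixed beforehand were the scalings named above, a filter on level at the 40th percentile, the mean of a gene's probe sets, eBayes with a trend and robust variances, array weights, only the arrays of the groups compared, blocks for the replicate or line number, an adjusted p below 0.01, a 2-fold minimum, and leaving out each array in turn. Alternatives added after the data were seen were the combinations of these with quantile normalization, the spike-in batch as a block, and the 3' minus 5' level of the actin and GAPDH controls as a covariate. Differences between arrays in RNA quality were read from those control probe sets.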

Results

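Gene expression was profiled in whole adult male fruit flies that express Dsup, the damage suppressor protein of a tardigrade, which binds nucleosomes and shields DNA. Control flies without the transgene were profiled beside them, and both kinds of flies were measured untreated and after 1000 Gy of ionizing radiation. The untreated control, the untreated Dsup lines 1 to 4 and the irradiated Dsup lines 1 to 4 gave 4 arrays each, and the irradiated control gave 3. Each array reports the log2 level of 18952 probe sets. The deposited array means were 4.64 in the untreated control, 4.05 in the untreated Dsup lines, 4.88 in the irradiated control and 4.51 in the irradiated Dsup lines, with little spread inside each group (SD 0.00655, 0.00368, 0.0109 and 0.00640, in that order). On those values the median of all probe sets moved by -0.61 between untreated control and Dsup lines, by -0.39 between irradiated control and Dsup lines, by 0.23 with radiation in control flies and by 0.47 in Dsup lines. In the interaction it moved by 0.23. After quantile normalization these medians lay between -0.01 and 0.02. In principal components of the quantile-normalized values of probe sets at or above the 40th percentile of level, PC1 held 49.1% of the variance and PC2 13.9%.

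**Figure D1:**
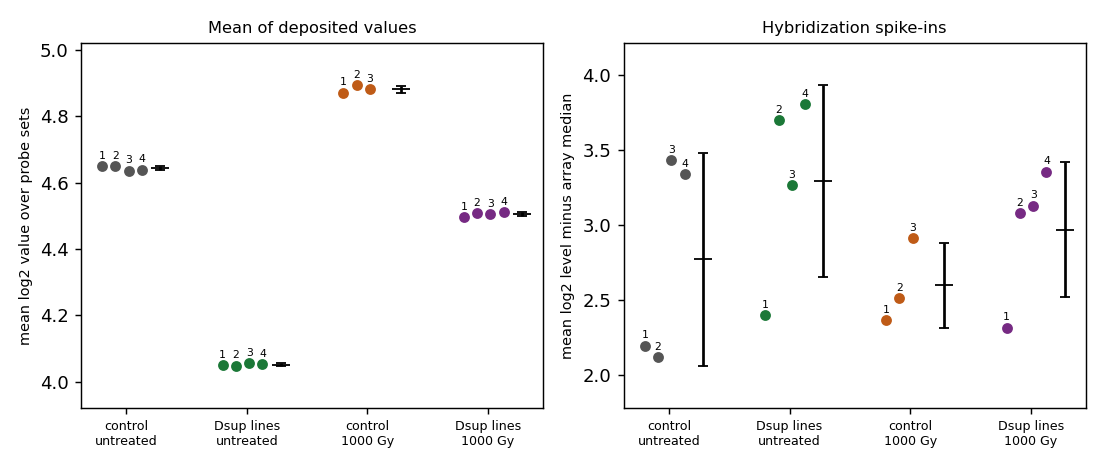
Left, the mean deposited log2 value of each array; right, the mean log2 level of the hybridization spike-ins minus the array's median. Points are arrays with their replicate or line number, grouped by genotype and treatment, and bars are the group mean with its SD: the 4 groups differ in mean by up to 0.830 while arrays of a group lie within 0.0217.

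The RNA quality controls differed between treatments. The 3' minus 5' log2 difference of the actin control probe sets was 0.994 in untreated control, 1.13 in untreated Dsup lines, 1.52 in irradiated control and 1.32 in irradiated Dsup lines, and that of GAPDH was 0.998, 1.12, 1.31 and 1.34. Untreated control 4 stood apart in 18S ribosomal RNA, whose 3' level relative to the array median was 3.11, against 6.90 to 8.18 in all other arrays.

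The first comparison asked how control flies responded to 1000 Gy (n = 3 irradiated, 4 untreated). Genes of the delta glutathione S-transferases, enzymes that conjugate glutathione to electrophiles, rose most: GstD5 by 5.16 ± 0.55 (SE) on the log2 scale, a 35.8-fold rise (adjusted p = 1.14e-05), GstD2 by 5.15 ± 0.67 and GstD4 by 4.91 ± 0.36. Some genes of the damage response rose with them, though camera did not call the DNA repair list as a whole. It had 11 of 34 members higher and 4 lower (median 0.14, camera adjusted p = 0.0891). RnrL, the large subunit of ribonucleotide reductase, rose by 2.47 ± 0.27 (adjusted p = 1.43e-05), Corp, a target of p53, by 1.52 ± 0.16 (adjusted p = 8.59e-06) and p53 itself by 0.87 ± 0.13 (adjusted p = 0.000197). The proapoptotic gene skl fell by 0.56 (adjusted p = 0.0022). Among the large falls were the odorant-binding protein genes Obp83b by 4.53 ± 0.81, a 23.1-fold fall (adjusted p = 0.000628), Obp19a by 3.94 ± 0.69 and Obp69a by 2.68 ± 0.60. Of the olfactory-specific genes, a5 fell by 3.88 ± 0.57, Os-C by 3.54 ± 0.58 and a10 by 3.47 ± 0.48.

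Other genes with large rises in irradiated control flies were CG5550 (4.50 ± 0.30), CG16898 (4.19 ± 0.34), CG33468 (3.73 ± 0.35), CG42365 (3.50 ± 0.37), fit, a secreted protein of the fat body (3.49 ± 0.67), and the Turandot stress gene TotC (4.56 ± 1.26, adjusted p = 0.0114). Of the 60 named genes called here, 59 kept the call when each array was left out in turn; TotC was not called without irradiated control 3, with an adjusted p of 0.0683. With the 3' minus 5' covariate 22 lost the call, with p up to 0.413 (rdgA): AANATL3, BomS2, Drs, EbpII, fit, Gadd45, Hsp68, inaE, Jhedup, MED10, MED16, mRpL17, mRpS18A, Obp69a, Obp99b, p53, rdgA, Rdl, Sfp38D, Sh, skl and TotC. Large falls were also measured in Jhedup, a juvenile hormone esterase duplicate (-3.31 ± 0.79), and in AANATL3, an arylalkylamine N-acetyltransferase (-3.21 ± 0.46). Yp1, a yolk protein of females, differed by 0.16 (adjusted p = 0.452). A probe set shared by Hsp70Aa and Hsp70Ab rose by 4.80 ± 1.01 (adjusted p = 0.00214), and by 3.51 ± 0.94 in Dsup lines (adjusted p = 0.0158). Within the spike-in batches, the changes were 5.28 and 4.89 for GstD5, 2.50 and 2.41 for RnrL, 1.54 and 1.49 for Corp, and -4.04 and -5.64 for Obp83b in the first and second batch.

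After quantile normalization 6384 probe sets were called, 3177 higher and 3207 lower, and 793 of them changed at least 2-fold (419 higher, 374 lower). Of the 6384, 2286 lay below the 40th percentile of level, and with all probe sets below it removed before testing 4054 were called. As deposited 9297 were called, 7862 higher and 1435 lower. The split was 3881 and 2814 after median centring, and 2193 and 4359 after ribosomal centring. Of the 6384, 4612 were called in the same direction on the deposited values. In the first spike-in batch 5046 probe sets were called. The changes in the 2 batches correlated across probe sets with r = 0.817, which the identical values shared by irradiated controls of both batches raise by themselves. With the 3' minus 5' level of the control genes as a covariate, 1686 were called.

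Of 30 gene lists, camera called 13 higher and 2 lower in irradiated control flies. In the p53 and radiation response list, 8 of 10 members rose and 1 fell, with 8 and 1 adjusted over the list alone, among them RnrL, Corp and the transcription factor gene Ets21C (1.29 ± 0.15). The median was 1.33 (1.34 and 1.31 within the batches; camera adjusted p = 0.000296). The antioxidant and glutathione list had 19 of 27 members higher and 2 lower (21 and 2 adjusted over the list alone), with GstD7 up by 1.74 and GstD8 by 2.01. Its median was 1.18 (1.11 and 1.37 within the batches; adjusted p = 6e-10). Of 9 heat shock and chaperone genes 7 rose (8 adjusted over the list alone), among them Hsp68 (2.18 ± 0.35), the small heat shock gene Hsp26 (2.15 ± 0.30) and the cochaperone gene stv (1.40 ± 0.19). The median was 0.79 (0.76 and 1.0; adjusted p = 0.00197). Of 7 JNK targets 5 rose (6 adjusted over the list alone), with Gadd45 up by 2.14 ± 0.33 and Jra, the fly Jun, by 0.80 ± 0.12 (median 0.79, 0.80 and 0.72 within the batches; adjusted p = 0.0104). With an estimated correlation, the adjusted p = 0.380 for these 4 lists.

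Of the male reproductive tract, the accessory gland list and the ejaculatory bulb and duct list were higher too. The testis list was not (6 of 45 members higher and 6 lower, median 0.02, camera adjusted p = 0.973). In the accessory gland list 25 of 34 members rose (27 adjusted over the list alone), with the seminal fluid genes Sfp24Bb up by 1.19 and Sfp38D by 1.0 (median 0.58, 0.48 and 0.89 within the batches; adjusted p = 6.02e-07). All 5 ejaculatory bulb and duct genes rose (5 adjusted over the list alone), with Dup99B up by 0.96, EbpIII by 0.52 and EbpII by 0.39 (median 0.52, 0.41 and 0.78; adjusted p = 0.0102). For both lists the adjusted p = 0.380 with an estimated correlation. In the fat body list 5 of 9 members rose (5 adjusted over the list alone), among them fit, Obp99b (2.02 ± 0.55) and Npc2h (0.89 ± 0.19). The median change was 1.11 (0.96 and 1.25; adjusted p = 0.015). Mitochondrial ribosomal proteins had 32 of 69 members higher and 1 lower (35 and 1 adjusted over the list alone), such as mRpS33 at 0.96, mRpL17 at 0.59 and mRpS18A at 0.56 (median 0.28, 0.31 and 0.21; adjusted p = 6.02e-07). General transcription factors had 16 of 50 members higher and 4 lower (16 and 4 adjusted over the list alone), with Polr2J up by 0.66, MED10 by 0.54 and MED16 by 0.53 (median 0.17, 0.20 and 0.08; adjusted p = 0.015). The adjusted p = 0.402 with an estimated correlation for these last 3 lists.

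Among replication and cell cycle genes 9 of 22 rose and 2 fell (9 and 2 adjusted over the list alone), with the origin recognition gene Orc1 up by 1.31 ± 0.14 and the replicative helicase genes Mcm2 by 0.94 and Mcm3 by 0.89. Across the list the median was 0.24 (0.25 and 0.15 within the batches; adjusted p = 0.0291, and adjusted p = 0.380 with an estimated correlation). Of 18 antimicrobial and humoral immunity genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Drs (1.44), BomS2 (1.12) and Drsl2 (0.86). All 18 had a median of 0.45 (0.35 and 0.26; adjusted p = 0.0291, 0.0667 without irradiated control 3, and adjusted p = 0.402 with an estimated correlation). Cuticle proteins had 27 of 105 members higher and 6 lower (27 and 6 adjusted over the list alone), such as Cpr60D at 1.21, Lcp65Ag3 at 1.04 and Cpr72Eb at 0.65. The median of the list was 0.17 (0.15 and 0.15). Their call (adjusted p = 0.0322, and adjusted p = 0.407 with an estimated correlation) ended without untreated control 2 (adjusted p = 0.0606), untreated control 4 (adjusted p = 0.0506) or irradiated control 3 (adjusted p = 0.0571). The odorant-binding family split: 15 of 47 members rose and 6 fell (18 and 6 adjusted over the list alone), with Obp22a up by 1.05, Obp51a by 0.75 and Obp56i by 0.73, while Obp83b, Obp19a and Obp69a fell. Its median was 0.18 (0.19 and 0.17 within the batches) and its mean -0.02, while camera placed it higher (adjusted p = 0.0322, 0.0528 without untreated Dsup line 3, and adjusted p = 0.380 with an estimated correlation).

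The neuron list fell, with 6 of 18 members lower and 0 higher (6 adjusted over the list alone), among them the channel genes para (-0.89), Sh (-0.88) and Rdl (-0.60). The median was -0.34 (-0.33 and -0.22 within the batches; adjusted p = 0.0121, and adjusted p = 0.407 with an estimated correlation). Another probe set of Sh was higher by 0.45 (adjusted p = 0.0341). The photoreceptor list had 7 of 18 members lower and 1 higher (7 and 1 adjusted over the list alone), with rdgA at -0.83, rdgC at -0.60 and inaE at -0.49. All 18 had a median of -0.30 (-0.31 and -0.32; adjusted p = 0.0238, and adjusted p = 0.380 with an estimated correlation). As deposited that median was 0.09, where the median of all probe sets was 0.23, and other probe sets of rdgC and inaE lay at 0.02 and 0.40. As deposited the calls of 6 of these 15 lists were absent, with adjusted p of 0.34 for immunity, 0.2 for cell cycle, 0.13 for photoreceptor, 0.097 for fat body, 0.62 for cuticle and 0.44 for odorant-binding proteins. The insulin and starvation response list, with 3 of 13 members higher and 6 lower, had a median of -0.83 and was not called (adjusted p = 0.156), but it was called lower as deposited (adjusted p = 0.0102) and by fry (adjusted p = 0.0192). Proteasome (adjusted p = 0.0102), cytosolic ribosomal (adjusted p = 0.00661) and oxidative phosphorylation (adjusted p = 0.000104) lists were called higher as deposited alone. After quantile normalization camera did not call the testis (0.02), muscle (-0.05), chromatin (0.07), proteasome (0.04), apoptosis (0.12) or Turandot (0.28) lists.

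The Dsup lines were compared with their own untreated flies in the same way (n = 4 and 4), to ask how flies with the transgene responded to 1000 Gy. Among the large rises of named genes were those of CG7142 (3.02 ± 0.17, an 8.09-fold rise, adjusted p = 3.12e-07), GstD4 (2.62 ± 0.34, adjusted p = 0.000135), CG16898 (2.46 ± 0.31), CG5550 (2.30 ± 0.28) and CG2065 (2.16 ± 0.33), followed by CG13868 (2.03), CG13482 (1.93), GstE7 (1.81) and the trypsin gene Try29F (1.81). CG34316 fell by 2.72 ± 0.18 (adjusted p = 7.92e-07) and Ser8, a serine protease, by 2.56 ± 0.21. Genes for a cytochrome P450 (Cyp4e3, -2.22), the olfactory coreceptor (Orco, -1.93 ± 0.28), the alkaline phosphatase Alp9 (-1.92), the endoderm transcription factor GATAe (-1.87), the insulin receptor (InR, -1.76 ± 0.31, adjusted p = 0.0014), CG8483 (-1.70) and odd (-1.58) fell too, as did AANATL3 (-2.17). Corp rose by 1.25 ± 0.14 (adjusted p = 5.32e-05) and p53 by 0.63 ± 0.12 (adjusted p = 0.00252), whereas skl fell by 0.43 (adjusted p = 0.0118; -0.01 as deposited). A second probe set of p53 stood at 0.03, and Yp1 at 0.14 (adjusted p = 0.494). Within the batches the changes were 4.14 and 2.12 for GstD4, 1.12 and 1.29 for Corp, 1.18 and 0.45 for p53, and -1.85 and -1.96 for Orco. All 37 named genes called here kept the call when each array was left out in turn, and Ilp8, Ku80 and Sfp24Bb lost it with the 3' minus 5' covariate (p up to 0.160 for Ku80).

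In the Dsup lines 3999 probe sets were called, 2011 higher and 1988 lower, of which 219 changed at least 2-fold (110 higher, 109 lower). Of the 3999, 1838 lay below the 40th percentile of level, and with all probe sets below it removed before testing 1918 were called. As deposited 14489 were called, 14258 higher and 231 lower. The split was 2301 and 1531 after median centring, and 838 and 2215 after ribosomal centring. Within the batches 754 and 3126 were called, with r = 0.530 across probe sets, and 2006 were called with the 3' minus 5' covariate. Across probe sets, the radiation responses of control flies and Dsup lines correlated with a Pearson coefficient of 0.683 and a Spearman coefficient of 0.552 (0.694 and 0.569 as deposited); probe sets are not independent replicates. Both genotypes had 977 rises in common, against 340 expected by chance from the numbers called, and 1134 falls, against 340 expected. Among probe sets called in control flies, the median ratio of the Dsup response to the control response was 0.431 (0.970 as deposited). Among those called in Dsup lines, the median ratio of the control response to the Dsup response was 0.760 (0.556 as deposited).

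Camera called 6 lists higher in irradiated Dsup lines and 0 lower; adjusted p = 0.833 with an estimated correlation for each of the 6. The antioxidant list had 13 of 27 members higher and 1 lower (14 and 1 adjusted over the list alone), with Gclm, a subunit of the enzyme that starts glutathione synthesis, up by 1.28 ± 0.18 and GstD7 by 0.88. Its median was 0.50 (0.84 and 0.31 within the batches; adjusted p = 0.000172). Of 10 p53 and radiation response genes 4 rose, 1 fell and 5 were not called (7 and 1 adjusted over the list alone), and Ku80, of the Ku complex that binds broken DNA ends, rose by 0.81 ± 0.21 (1.82 and 0.47 within the batches). This p53 list had a median of 0.40 (0.82 and 0.30; adjusted p = 0.0457). That call ended with the Dsup line block (adjusted p = 0.0533), without untreated control 1 (0.0503), untreated Dsup line 1 (0.0613), 2 (0.0556) or 3 (0.112), and without irradiated Dsup line 1 (0.121). Of 7 JNK targets 3 rose (5 adjusted over the list alone): Gadd45 by 1.61, Jra by 0.89 and Ilp8, a relaxin-like growth signal, by 0.48 (median 0.35, 0.30 and 0.38 within the batches; adjusted p = 0.0124).

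The accessory gland list had 7 of 34 members higher (7 adjusted over the list alone), with the seminal metalloprotease gene Semp1 up by 0.85, Acp95EF by 0.70 and Sfp24Bb by 0.57 (median 0.29, 0.13 and 0.36 within the batches; adjusted p = 0.000442). Mitochondrial ribosomal proteins had 18 of 69 members higher (19 adjusted over the list alone), with mRpS14 at 0.58, mRpS6 at 0.48 and mRpL45 at 0.43 (median 0.16, 0.04 and 0.20; adjusted p = 0.000548). Oxidative phosphorylation genes had 9 of 71 members higher and 2 lower (8 and 2 adjusted over the list alone), with ND-B12 at 0.70, ND-20L at 0.39 and Cyt-c1L at -0.41 (0.11 as deposited). The median was 0.10 (-0.04 and 0.14) and the call (adjusted p = 0.0147) ended without line 4, untreated (adjusted p = 0.0564) or irradiated (adjusted p = 0.144). As deposited, the p53 list (adjusted p = 0.67) and the JNK targets (adjusted p = 0.17) were not called. Called as deposited alone were insulin and starvation response (adjusted p = 0.00028), neuron (adjusted p = 0.0139) and antimicrobial (adjusted p = 0.0161) lists, lower, and cytosolic ribosomal (adjusted p = 6.21e-06), proteasome (adjusted p = 0.000950) and testis (adjusted p = 0.0247) lists, higher.

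**Figure D2:**
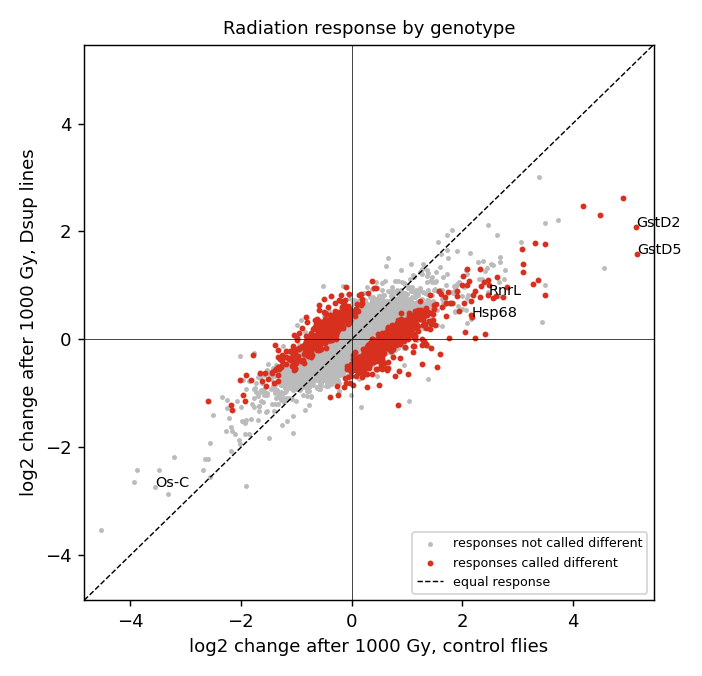
Log2 change after 1000 Gy in control flies (horizontal axis) against that in Dsup lines (vertical axis), 1 point per gene, quantile-normalized values, n = 3 against 4 and 4 against 4 arrays. Red points are genes whose responses were called different, and the dashed line marks equal responses: GstD5, GstD2, RnrL and Hsp68 lie below it.

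Irradiated Dsup lines were then compared with irradiated control flies (n = 4 and 3), to ask whether flies with the transgene differed after the same dose. The UDP-glycosyltransferase gene Ugt302K1, whose mean level lies below the 40th percentile, was lower in the Dsup lines by -2.61 ± 0.30 on the log2 scale, a 6.09-fold difference (adjusted p = 0.000146; -1.84 and -2.47 within the batches), the cytochrome P450 gene Cyp6d2 by -2.25 ± 0.38 (adjusted p = 0.00198; -1.02 and -2.59) and GstD4 by -2.13 ± 0.36 (adjusted p = 0.00193; -1.25 and -2.01). Irbp, the fly Ku70, which binds broken DNA ends with Ku80, had a mean level of 4.88 in the irradiated Dsup lines and 6.32 in irradiated control flies, a difference of -1.44 ± 0.29 (adjusted p = 0.00505; -0.32 and -1.76), against 4.05 and 4.21 in untreated flies. Hsp26 was lower by -1.70 ± 0.30 (-0.59 and -2.29) and Hsp68 by -1.61 ± 0.35 (-0.19 and -2.44).

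Other genes lower in irradiated Dsup lines were the noncoding RNA of the alphagamma heat shock element CR32865 (-2.39 ± 0.62), GstD2 (-2.17 ± 0.67), CG3448 (-2.07 ± 0.33), CG32284 (-1.86 ± 0.56, adjusted p = 0.0426, and 0.0636 with the Dsup line block) and CG5290 (-1.61 ± 0.34). Higher in irradiated Dsup lines were CG13607 (1.98 ± 0.42, adjusted p = 0.00672), CG15263 (1.42 ± 0.29), CG42329 (1.17), CG31664 (1.16), CG8834 (1.04), the cytochrome P450 gene Cyp6a2 (1.0), Acsx3 (0.99), comm2 (0.93), Acp95EF (0.91) and Pgant2 (0.88). Another probe set of Pgant2 stood at -0.23 and was not called. The genes skl (-0.07), Corp (-0.40, adjusted p = 0.114), p53 (-0.28, adjusted p = 0.202) and Yp1 (-0.02) were not called. Of the 35 named genes called, 29 kept the call when each array was left out in turn. The others were CG42329 (p up to 0.0973, without irradiated control 3), CG8834 (0.0625) and Cyp6a2 (0.128), both without irradiated control 2, CR32865 (0.0875) and CG32284 (0.171), both without irradiated control 1, and GstD2 (0.165, without irradiated control 2). CG32284, Cyp6a2 and GstD2 also lost the call with the 3' minus 5' covariate (p up to 0.0868 for GstD2) and with the level filter (p up to 0.0916 for GstD2).

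In this comparison 2258 probe sets were called, 1120 higher and 1138 lower in Dsup lines, and of the 88 that differed at least 2-fold 18 were higher and 70 lower. Of the 2258, 1436 lay below the 40th percentile of level, and with all probe sets below it removed before testing 477 were called. As deposited 11606 were called, 291 higher and 11315 lower. The split was 3228 and 1004 after median centring, and 3175 and 687 after ribosomal centring. Without irradiated control 2, 1055 were called after quantile normalization. Within the batches 45 and 445 were called, with r = 0.589 across probe sets.

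Camera called 6 lists lower in irradiated Dsup lines and 0 higher; adjusted p = 0.562 with an estimated correlation for each of the 6. Of 10 p53 and radiation response genes 6 were lower and 4 not called (7 lower adjusted over the list alone), among them Irbp, Traf4 (-1.08; another probe set -0.13, adjusted p = 0.477) and Ets21C (-0.73). The median was -0.75 (-0.25 and -0.89 within the batches; adjusted p = 3.75e-05). The antioxidant list had 12 of 27 members lower and 1 higher (13 and 1 adjusted over the list alone), with GstD6 at -1.13 and Gclc, the catalytic subunit for glutathione synthesis, at -0.48 (median -0.48, -0.17 and -0.49; adjusted p = 2.28e-05). Of 9 heat shock genes 5 were lower (7 adjusted over the list alone), with stv at -1.08 ± 0.19 (median -0.50, -0.19 and -0.60; adjusted p = 0.000334). DNA repair genes had 11 of 34 members lower and 3 higher (12 and 3 adjusted over the list alone), with XRCC1, a scaffold of strand break repair, at -0.76 and the endonuclease gene mus81 at 0.53 ± 0.07 (median -0.21, -0.09 and -0.25; adjusted p = 0.000871, and 0.18 as deposited).

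The antimicrobial list had 3 of 18 members lower (4 adjusted over the list alone), the drosomycin-like genes Drsl3 (-1.64), Drsl2 (-0.71) and Drsl1 (-0.49), whose mean levels lie below the 40th percentile. The median change was -0.39 (-0.02 and -0.65 within the batches). Its test was lower after quantile normalization (adjusted p = 0.0166) and turned to higher, not called, as deposited (adjusted p = 0.85). The call also ended without irradiated control 3 (adjusted p = 0.08) or irradiated Dsup line 3 (adjusted p = 0.0857). Of 22 replication and cell cycle genes 4 were lower and 1 higher (6 and 1 adjusted over the list alone), with Orc1 at -1.24 ± 0.14, Mcm2 at -0.60 and the E2F partner Dp at 0.43 (-0.04 as deposited). Across the list the median was -0.18 (-0.08 and -0.19), and the call (adjusted p = 0.0243, and 0.069 as deposited) ended without irradiated control 3 (adjusted p = 0.0604) or irradiated Dsup line 2 (adjusted p = 0.0505). Called as deposited alone were, higher relative to all probe sets, midgut (adjusted p = 0.000344), cytochrome P450 (adjusted p = 0.000556), cuticle (adjusted p = 0.00163), odorant-binding (adjusted p = 0.00365), muscle (adjusted p = 0.0184) and insulin and starvation (adjusted p = 0.0193) lists. Mitochondrial ribosomal (adjusted p = 4.25e-06), transcription (adjusted p = 0.000478) and proteasome (adjusted p = 0.0127) lists were called lower.

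**Figure D3:**
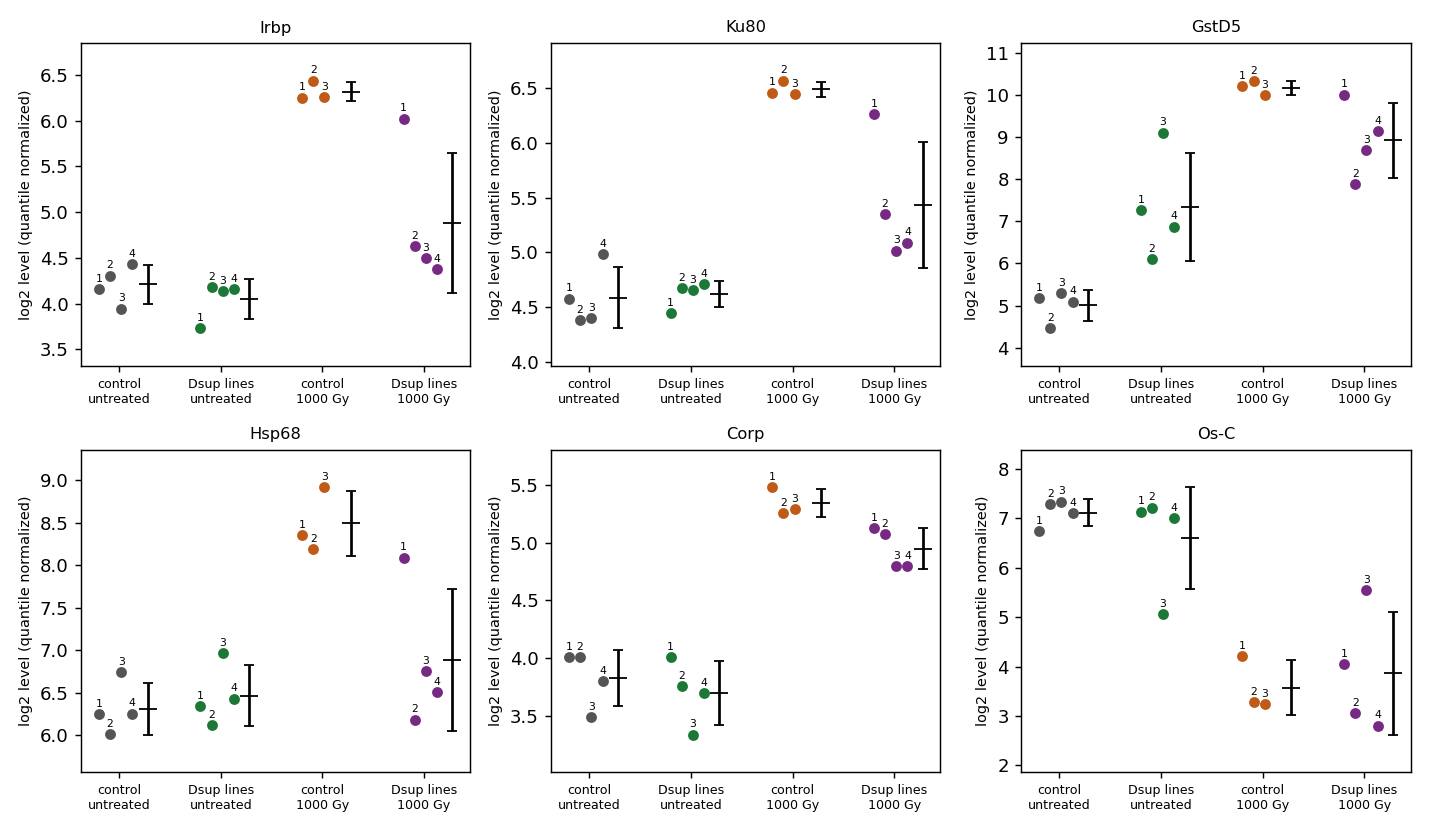
Log2 levels after quantile normalization of Irbp, Ku80, GstD5, Hsp68, Corp and Os-C in the 15 arrays. Points are arrays with their replicate or line number, grouped by genotype and treatment, and bars are the group mean with its SD; Irbp averaged 6.32 in irradiated control flies and 4.88 in irradiated Dsup lines.

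The interaction asked whether the response to radiation itself differed between genotypes, as the change in Dsup lines minus the change in control flies. The rise of delta glutathione S-transferases was smaller in Dsup lines: the responses differed by -3.58 ± 0.75 for GstD5 (adjusted p = 0.00908; -2.54 and -3.69 within the batches) and by -2.28 ± 0.49 for GstD4 (adjusted p = 0.0106; -0.98 and -2.40). For GstD5 the larger part of this value came from untreated flies, where its level was already higher in Dsup lines. For GstD4 the larger part came from irradiated flies, where its level was lower in Dsup lines. RnrL differed by -1.64 ± 0.37 (adjusted p = 0.0133; -1.03 and -1.79), Orc1 by -1.35 ± 0.19 (adjusted p = 0.000928; -1.12 and -1.25), and Ugt302K1 by -2.68 ± 0.41 (adjusted p = 0.00159; -1.69 and -2.58). The mean levels of Orc1 and Ugt302K1 lie below the 40th percentile. The responses of Corp (-0.27, adjusted p = 0.474), p53 (-0.24, adjusted p = 0.461), skl (0.13, adjusted p = 0.684) and Yp1 (-0.02, adjusted p = 0.977) were not called different, though a second probe set of p53 was (-0.44, adjusted p = 0.0326).

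GstD2 (-3.07 ± 0.91, adjusted p = 0.0484) and CtsL3, a cathepsin L (-2.32 ± 0.65), also had a smaller response in Dsup lines. Ugt37A3 was not called (-3.12 ± 1.0, adjusted p = 0.0675) except with the Dsup line block (0.0488). The opposite sign was found for GstT4, a theta glutathione S-transferase (1.26 ± 0.26, adjusted p = 0.00883), the kinase gene Drak (1.25 ± 0.20, adjusted p = 0.00216), the glycerol kinase gene Gk2 (1.13 ± 0.22), CG15263 (1.46 ± 0.39) and CG9377 (1.28 ± 0.36). CG13607 (1.71, adjusted p = 0.0759) and slow (1.27, adjusted p = 0.071) were not called. GstT4 averaged 9.90 in untreated and 7.88 in irradiated control flies, and 9.44 and 8.68 in Dsup lines. Of 35 named genes called in the interaction, 21 kept the call when each array was left out in turn. Hsp26 lost it only without irradiated control 3 (adjusted p = 0.0549). The other 13, with p up to 0.128 (EbpII, without irradiated control 1), were CG15263, CG9377, CtsL3, EbpII, GstD2, Hsp27, Hsp68, Irbp18, Mcm3, MED10, Obp22a, Obp57b and Taf10. With the 3' minus 5' covariate 17 lost the call, with p up to 0.153 (GstD2): these 13 and Hsp26, mRpS2, Obp50e and RnrL. With the level filter, which leaves weakly expressed genes untested, 15 lost it, with p up to 0.109 (GstD2), the same genes except Mcm3 and Obp50e.

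In the interaction 1704 probe sets were called, 809 higher and 895 lower, and of the 171 that differed at least 2-fold 44 were higher and 127 lower. Of the 1704, 1167 lay below the 40th percentile of level, and with all probe sets below it removed before testing 137 were called. As deposited 4298 were called, 3863 higher and 435 lower. The split was 691 and 788 after median centring, and 573 and 512 after ribosomal centring. Of the 1704, 1230 were also called in the response of control flies, and 1129 of these had a smaller response in Dsup lines. The same control arrays enter the interaction and the control response, so selecting on both favours a smaller Dsup response by itself. The share to be found without a difference was not computed, so 1129 of 1230 is no separate evidence. A further 423 were called only in the Dsup response and 51 in neither. The count was 866 without irradiated control 2, and 956 with the 3' minus 5' covariate. Within the batches 20 and 157 were called, with r = 0.541 across probe sets.

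Camera called 12 lists lower and 2 higher in the interaction. Of 10 p53 and radiation response genes 4 were lower (6 adjusted over the list alone), among them RnrL, Ets21C (-0.94) and Irbp18 (-0.92). All 10 had a median of -0.89 (-0.23 and -1.0 within the batches; adjusted p = 0.00242, and adjusted p = 0.461 with an estimated correlation). Of 27 antioxidant genes 11 were lower (18 adjusted over the list alone), with GstD6 at -1.34 and Gclc at -0.54 (median -0.84, -0.43 and -0.91; adjusted p = 4.23e-09, and adjusted p = 0.427 with an estimated correlation). Hsp68 (-1.76 ± 0.48), Hsp26 (-1.70 ± 0.41) and Hsp27 (-0.97 ± 0.28) were the 3 of 9 heat shock genes called lower (4 adjusted over the list alone). The median of the list was -0.55, but 0.02 in the first batch and -0.76 in the second (adjusted p = 0.007, and adjusted p = 0.478 with an estimated correlation). The responses of the Hsp70 probe sets were not called different: -1.29 ± 1.38 for that of Hsp70Aa and Hsp70Ab (adjusted p = 0.614), and -1.89, -1.87, -0.45 and 0.19 for 4 of the Hsp70B genes (adjusted p = 0.392, 0.360, 0.0885 and 0.744), the last shared with CG31343. The third of these 4 rose in control flies by 0.55 (adjusted p = 0.00214), was not called in Dsup lines (0.10, adjusted p = 0.556) and was lower in irradiated Dsup lines than in irradiated control flies (-0.64, adjusted p = 0.00255). In the antimicrobial list 4 of 18 members were lower and 1 higher (4 and 1 adjusted over the list alone), with the weakly expressed Drsl3 at -2.05, Drsl2 at -1.44 and Drsl1 at -0.68 (median -0.42, -0.25 and -0.53; adjusted p = 0.0159, and adjusted p = 0.478 with an estimated correlation). Cell cycle genes had 3 of 22 members lower (4 adjusted over the list alone), Orc1, Mcm2 (-0.80) and Mcm3 (-0.40). All 22 had a median of -0.20 (-0.20 and -0.16; adjusted p = 0.007, and adjusted p = 0.427 with an estimated correlation).

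DNA repair genes had 5 of 34 members lower and 1 higher (6 and 1 adjusted over the list alone), with the endonuclease genes mei-9 at -0.77 and mus81 at 0.59. For the repair list the median was -0.14 (-0.09 and -0.05 within the batches; adjusted p = 0.016, 0.0711 without irradiated Dsup line 4, and adjusted p = 0.623 with an estimated correlation). General transcription genes had 3 of 50 members lower (2 adjusted over the list alone), MED16 (-0.56), MED10 (-0.46) and Taf10 (-0.37; adjusted p = 0.0657 with the Dsup line block). The median change was -0.13 (-0.04 and -0.05; adjusted p = 0.0126, 0.067 as deposited, and adjusted p = 0.478 with an estimated correlation). Odorant-binding proteins had 4 of 47 members lower (3 adjusted over the list alone), such as Obp22a (-0.70), Obp57b (-0.64; 0.0569 with the line block) and Obp50e (-0.56). Across the list the median was -0.14 (-0.25 and -0.09; adjusted p = 0.0253, and adjusted p = 0.427 with an estimated correlation). That call ended without untreated Dsup line 1 (adjusted p = 0.0611) or irradiated Dsup line 4 (adjusted p = 0.053). Mitochondrial ribosomal proteins had 2 of 69 lower (2 adjusted over the list alone), mRpS33 (-0.75) and mRpS2 (-0.74). All 69 had a median of -0.12 (-0.23 and 0.00). Their adjusted p was 0.00897, 0.105 without untreated control 2, 0.0577 without untreated Dsup line 1, and adjusted p = 0.706 with an estimated correlation. As deposited, the medians of the cell cycle (0.03), DNA repair (0.12), transcription (0.06), odorant-binding (0.05) and mitochondrial ribosomal (0.04) lists were above 0 and below the median of all probe sets of 0.23.

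The accessory gland list (median -0.31, -0.41 and -0.56 within the batches) and the fat body list (median -0.80, -0.36 and -1.0) were lower with 0 members called by limma and 0 adjusted over the list alone. At an unadjusted p below 0.05, 4 of 34 members were lower and 1 higher in the first list, and 4 of 9 lower in the second. Spn77Bc, a serpin of the accessory gland, stood at -0.87 (adjusted p = 0.109), fit at -2.49 (adjusted p = 0.102) and apolpp, the lipoprotein of the hemolymph, at -0.88 (adjusted p = 0.0591). The accessory gland adjusted p of 0.007 became 0.0546 without untreated control 4 (adjusted p = 0.692 with an estimated correlation), and that of the fat body list was 0.00897 (adjusted p = 0.478 with an estimated correlation). Of 5 ejaculatory bulb genes 1 was lower, EbpII (-0.39; 0.0582 with the line block), with 2 adjusted over the list alone and Gld at -0.98 (adjusted p = 0.0854, 0.0497 with the line block). The median of the list was -0.39 (-0.45 and -0.58; adjusted p = 0.00897, and adjusted p = 0.478 with an estimated correlation). These 3 lists differed between genotypes more before than after radiation: in untreated flies the medians of Dsup lines minus control were 0.30, 0.95 and 0.35, and at 1000 Gy they were 0.01, 0.09 and -0.05 (camera adjusted p = 0.774, 0.948 and 0.549). Cytosolic ribosomal proteins (median 0.09, 0.13 and 0.08) and oxidative phosphorylation genes (median 0.10, 0.01 and 0.07) were higher by camera, with 0 members called by limma over all genes or the list alone, and at an unadjusted p below 0.05 with 4 of 41 higher and with 3 of 71 higher and 1 lower. The first call (adjusted p = 0.0159) ended without untreated control 3 (adjusted p = 0.0545), untreated Dsup line 1 (0.0577) or 2 (0.0863). The second (adjusted p = 0.0161) ended without untreated control 1 (0.0559) or 3 (0.0603), or line 4 untreated (0.0765) or irradiated (0.11). For both, adjusted p = 0.692 with an estimated correlation, and neither was called after median centring (0.4 and 0.49).

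The last comparison asked how untreated flies of the Dsup lines differed from untreated control flies (n = 4 and 4). Among the genes higher in the Dsup lines were Ugt37A3 by 2.73 ± 0.68 on the log2 scale, a 6.61-fold difference (adjusted p = 0.0207; 1.79 and 4.05 within the batches), GstD5 by 2.33 ± 0.51 (adjusted p = 0.011; 2.29 and 2.26), Cyp4d21 by 1.87 ± 0.46 and Ugt37A2 by 1.65 ± 0.30 (adjusted p = 0.00381; 1.20 and 2.17). The fat body genes fit (2.35 ± 0.62, adjusted p = 0.0257) and Lsp2, a storage protein (1.86 ± 0.55, adjusted p = 0.0442, and 0.0739 with the Dsup line block), were higher too. Lower in the Dsup lines were Sclp (-1.07 ± 0.26, adjusted p = 0.0172), the secreted phospholipase gene GIIIspla2 (-1.06 ± 0.27, adjusted p = 0.0226) and the immune peptide gene BomT2 (-1.04 ± 0.28, adjusted p = 0.0279). The genes skl (-0.20), Corp (-0.13), p53 (-0.04, adjusted p = 0.872) and Yp1 (0.00, adjusted p = 0.996) were not called, and 0 of 10 members of the p53 and radiation response list were called by limma, over all genes or over the list alone or at an unadjusted p below 0.05 (median -0.05; camera adjusted p = 0.956).

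Higher in untreated Dsup lines were also CG14499 (2.46 ± 0.54), CG14500 (1.65 ± 0.33), CG18258 (1.58 ± 0.40) and CG3984 (1.33 ± 0.36; 0.62 with an adjusted p of 0.1 as deposited). The remaining named genes that were lower were CG33093 (-1.12 ± 0.31, adjusted p = 0.0328, and 0.0542 with the line block), CBP, a calcium-binding protein (-0.87), the chitinase gene Cht8 (-0.78), mthl15 (-0.70), CG32267 (-0.66 ± 0.10, adjusted p = 0.00152), CG31077 (-0.57) and ARY (-0.57 ± 0.11). The cuticle gene Cpr67Fb (-1.74, adjusted p = 0.0935), CG15649 (-1.01, adjusted p = 0.0519) and the defensin gene Def (-0.86, adjusted p = 0.0883) had been called as deposited; with the line block the last 2 had p of 0.0326 and 0.0313. Of the 33 named genes called, 15 kept the call when each array was left out in turn. The other 18, with p up to 0.107 (CBP, without untreated Dsup line 3), included fit (0.0581, without untreated control 2), Lsp2 (0.103, without untreated Dsup line 3), Ugt37A3 (0.0624, without untreated control 2), GIIIspla2, BomT2 and, without untreated Dsup line 3 alone, mthl15 (0.053). With the 3' minus 5' covariate 11 lost the call, with p up to 0.0941 (CG33093): BomT2, CG33093, CG3984, cnc, fit, GIIIspla2, Gld, Lsp2, mRpS2, Obp22a and Obp57c. With the level filter 17 lost it, with p up to 0.0845 (Lsp2), the same genes except mRpS2 and also CBP, CG18258, CG31077, Cht8, EbpIII, Spn77Bc and Ugt37A3.

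Between untreated genotypes 2003 probe sets were called, 1018 higher and 985 lower in Dsup lines, and of the 48 that differed at least 2-fold 42 were higher and 6 lower. Of the 2003, 1240 lay below the 40th percentile of level, and with all probe sets below it removed before testing 323 were called. As deposited 16742 were called, 50 higher and 16692 lower. The split was 2616 and 555 after median centring, and 2036 and 357 after ribosomal centring. Of the 2003, 1035 were called in the same and 248 in the opposite direction as deposited. Within the batches 126 and 327 were called, with r = 0.616 across probe sets. The differences between genotypes in untreated and in irradiated flies correlated across probe sets with a Pearson coefficient of 0.133 and a Spearman coefficient of 0.125 (0.241 and 0.286 as deposited). They had 123 probe sets higher in both, against 60.7 expected from the numbers called, 112 lower in both, against 59.7 expected, and 153 called in opposite directions. The number of opposite calls to be expected was not computed. Both comparisons share 1 estimate of the spread of a probe set, which by itself raises the overlap of calls in either direction. These overlaps therefore do not show agreement.

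Camera called 7 lists higher in untreated Dsup lines and 0 lower. The accessory gland list had 1 of 34 members higher, Spn77Bc (0.77 ± 0.22, adjusted p = 0.0361), and 0 adjusted over the list alone; Sfp24Bb stood at 0.45 (adjusted p = 0.0692), and the list median was 0.30 (0.44 and 0.60 within the batches; adjusted p = 4.87e-06, and adjusted p = 0.537 with an estimated correlation). Untreated control 4, the array with low 18S ribosomal RNA, had a level of this list 0.36 below the control mean (-0.36). Of 9 fat body genes 3 were higher (6 adjusted over the list alone), fit, Lsp2 and the lipid transfer protein gene Mtp (0.50; -0.18 as deposited). All 9 had a median of 0.95 (0.66 and 0.79; adjusted p = 0.000387, and adjusted p = 0.537 with an estimated correlation). Of 5 ejaculatory bulb genes 2 were higher (3 adjusted over the list alone), the glucose dehydrogenase gene Gld (0.84) and EbpIII (0.35; -0.17 as deposited). All 5 had a median of 0.35 (0.17 and 0.50; adjusted p = 0.00845, and adjusted p = 0.537 with an estimated correlation). Odorant-binding proteins had 7 of 47 members higher (9 adjusted over the list alone), with Obp57a at 0.92 ± 0.18, Obp22a at 0.49 (-0.18 as deposited) and Obp57c at 0.42 (-0.24 as deposited). The median was 0.12 (0.17 and 0.07; adjusted p = 0.000965, and adjusted p = 0.0868 with an estimated correlation).

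The antioxidant list had 2 of 27 members higher, with 2 adjusted over the list alone: GstD5 and cnc, the regulator of antioxidant genes, at 0.29 (-0.39 as deposited, -0.01 for the mean of its probe sets). GstE6 stood at 0.53 (adjusted p = 0.0879). The list level was 0.33, 0.11, 0.71 and 0.16 in untreated lines 1 to 4, so line 3 stood highest, as it did in the fat body list (2.12). The median was 0.21 (0.18 and 0.39 within the batches; adjusted p = 0.000965, and adjusted p = 0.663 with an estimated correlation). The cytochrome P450 list, which took every symbol of Cyp followed by a digit, had 9 of 83 members higher and 1 lower (10 and 1 adjusted over the list alone). Cyp313a3 stood at 0.49 and Cyp6a19 at 0.48. Cyp40, at -0.40, is a cyclophilin gene and not a cytochrome P450, so the list is not made of cytochromes P450 alone. The median was 0.13, but -0.05 in the first batch and 0.20 in the second (adjusted p = 0.00714, 0.0553 without untreated Dsup line 4, and adjusted p = 0.537 with an estimated correlation). Mitochondrial ribosomal proteins had 2 of 69 members higher, mRpS33 (0.59; -0.09 as deposited) and mRpS2 (0.49; -0.20 as deposited), and 2 adjusted over the list alone. The median change was 0.08 (0.17 and -0.02). They were higher after quantile normalization (adjusted p = 0.0338), lower as deposited (adjusted p = 0.0096) and not called after median centring (adjusted p = 0.28). The adjusted p was 0.447 without untreated control 2, 0.286 without untreated Dsup line 1, 0.172 without untreated Dsup line 3, and adjusted p = 0.959 with an estimated correlation. As deposited, the medians of the accessory gland (-0.31), ejaculatory bulb (-0.17), odorant-binding (-0.42), antioxidant (-0.40) and cytochrome P450 (-0.51) lists were below 0 and above the median of all probe sets of -0.61. Called as deposited alone were, higher relative to all probe sets, antimicrobial (adjusted p = 2.27e-07), midgut (adjusted p = 1.79e-06), cuticle (adjusted p = 3.61e-05), insulin and starvation (adjusted p = 0.00597) and muscle (adjusted p = 0.0295) lists. Cytosolic ribosomal (adjusted p = 0.00059), oxidative phosphorylation (adjusted p = 0.00637), proteasome (adjusted p = 0.00862) and transcription (adjusted p = 0.0435) lists were called lower.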

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

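Of the tests weighed in this part, those of the group offset, of the processing batch, of the lines ranked against the lowest irradiated control, of the nerve and eye lists and of untreated line 3 were chosen only after the result was seen. The test for a mislabelled line 1, the second set of antennal genes and all regroupings of arrays were fixed before.

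The deposited array means agree within each group and differ between groups. Separate normalization of each group would give this, and the widest range within a group was 0.0261 of the range of the group means. A true change of total RNA was not settled: the hybridization spike-ins, added in 1 amount, differed between untreated Dsup lines and controls by -0.16 ± 0.468 (SE), which includes both 0 and the median shift of all probe sets of -0.61. Directions that hold only on the deposited values may come from this offset.

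In the interaction 4 of 10 p53, 11 of 27 antioxidant and 3 of 9 heat shock genes were lower in Dsup lines, though no list was called with an estimated correlation (adjusted p = 0.461, 0.427 and 0.478) and the heat shock median was 0.02 in the first batch. An additive processing batch as the reason why irradiated line 1 lay nearest the irradiated controls was not settled. In untreated arrays the 18 called members differed between the inferred batches by -0.0179 ± 0.20 (SE). Line 1 exceeded the other irradiated lines by 0.83, and at least 0.41 was needed. The only untreated Dsup array of the first batch was line 1, and the only untreated control of the second was control 4. With so few arrays that SE does not part the difference from 0.41. A separate irradiation session for line 1 stays open. A control mislabelled as line 1 was not settled. On 10 probe sets chosen on the other arrays to part the genotypes, line 1 lay at 0.785 of the way from irradiated controls (-0.10 to 0.05) to the other irradiated Dsup lines (0.74 to 1.26). But untreated Dsup line 2 lay at -0.13, near the irradiated controls. Across all values the closest array of irradiated line 1 was irradiated control 2. Its r was 0.9941, 0.9941 and 0.9931 with irradiated controls 1 to 3, and 0.9924, 0.9938 and 0.9923 with irradiated Dsup lines 2 to 4. A weaker response of the Dsup lines may explain the lower list members, though the same arrays raised the idea. The mean over 46 members was below the lowest irradiated control (1.29) in 4 of 4 lines (1.09, 0.47, 0.61 and 0.67). Whether the transgene or the genetic background of the lines would cause it cannot be told apart here.

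The mean of 11 antennal genes, picked after their values were seen, was low in all irradiated arrays and in untreated Dsup line 3 (-2.18). Less antennal tissue or RNA in those samples may be the cause and was not settled. In the second antennal set only Obp84a, 1 of 17, was bright enough to be kept, at -2.16 in control flies. Of the dim ones, Amt (-0.97), Obp59a (-0.88), Or43a (-0.37), Ir64a (-0.36) and Ir40a (-0.30) were called lower there. Or47b (0.47, adjusted p = 0.00307) and Or83c (0.48, adjusted p = 0.00252) were called higher, and the others were not called. For a general loss of RNA from nerve and sense organs a fall to -1.08 was needed, a bar set from Obp84a alone. The neuron list had a median of -0.34 (SE of the list level 0.106) and the photoreceptor list one of -0.30 (SE 0.0465). Both lists fell less than that bar but were called lower, so a bar from 1 gene cannot decide this. Irradiated flies labelled as untreated line 3 were not settled: its p53 list level of -0.10 lay below the other untreated arrays (-0.07 to 0.12) and the lowest irradiated one (0.19), but its antioxidant list level of 0.71 was above that of irradiated line 2 (0.64) and its closest array was irradiated line 3. No biological cause of the antennal pattern was tested.

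Regrouping the arrays of a comparison gave the following. On deposited values the real grouping called the most in 1 of 35 ways for each simple contrast, the real one counted: 16742 against at most 1005 for untreated flies, 11606 against 5559 for irradiated flies, 9297 against 5180 for radiation in control flies and 14489 against 84 in Dsup lines. An offset common to a group gives this by itself, so these 4 deposited counts do not show whether chance is excluded. For the interaction 6 of 100 groupings called as many as the real 4298, up to 16107, so the deposited count may reflect the structure of the samples. After quantile normalization the real grouping was again 1 of 35, with 2003 against 253, 2258 against 1375, 6384 against 3085 and 3999 against 18, and for the interaction 1 of 100, with 1704 against 764. An offset of single probe sets from separate normalization would remain there and also favour the real grouping, as would the 6814 to 7744 identical values that pairs of irradiated controls share. So these counts do not show that chance is excluded either.

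In 43 of 582 groups of 4 arrays, 1 array lay far from the other 3. Chance flags about 1 in 20 groups, or 29.1 here. By array, irradiated Dsup line 1 had 11 of them, untreated control 4 had 8 and untreated Dsup line 3 had 6. The levels in this paragraph and the next are log2 values after quantile normalization. Irradiated line 1 was high in GstE6 (10.2), CG32284 (3.86), CG5290 (5.64), Irbp (6.02), CG16898 (10.8), MED10 (6.98), Irbp18 (7.42), mei-9 (3.35) and the apoptosis list (0.0669), and low in CG8834 (7.33) and Cyt-c1L (7.18). Untreated control 4 was low in Spn77Bc (9.97), Sfp24Bb (8.10), CG8834 (8.93), Rdl (5.84), Semp1 (4.26) and the accessory gland list (-0.36), and high in the chromatin (0.0772) and testis (0.0844) lists. Untreated line 3 was low in ARY (3.71), a5 (3.56), Os-C (5.07) and Obp69a (3.89), and high in the proteasome (0.14) and fat body (2.12) lists.

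Untreated control 2 was low in Ugt302K1 (1.60), CG31664 (3.17), Polr2J (5.08), Alp9 (6.94) and mei-9 (3.11). Untreated line 1 was low in Irbp (3.73) and Cpr72Eb (1.99) and high in Obp51a (9.90) and Drak (4.95). Irradiated line 4 was low in Obp51a (9.87) and high in Taf10 (6.36) and the cytochrome P450 list (0.15). Irradiated line 3 was high in a10 (5.67) and low in Jra (6.63). Untreated control 1 was low in a5 (5.77) and rdgC (6.11), untreated control 3 was high in the heat shock list (0.32), and untreated line 4 was low in the midgut list (-0.0455). List values are means over members relative to untreated controls.

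Of 119 genes named for a change between irradiated and untreated flies or for the difference of the responses, 44 had responses that differed between genotypes in the interaction test, 36 lower and 8 higher in Dsup lines. Part of these genes were named because they were called there or belong to lists lower there, and over all probe sets 895 were lower and 809 higher. Lower by more than 1 log2 unit were GstD5 (-3.58), GstD2 (-3.07), Ugt302K1 (-2.68), CtsL3 (-2.32), GstD4 (-2.28), CG5550 (-2.20), Drsl3 (-2.05), Hsp68 (-1.76), CG42365 (-1.74), CG16898 (-1.73), Hsp26 (-1.70), RnrL (-1.64), Drsl2 (-1.44), Orc1 (-1.35), GstD6 (-1.34) and Ku80 (-1.10). Lower by less were GstD8 (-0.99), Hsp27 (-0.97), Ets21C (-0.94), Irbp18 (-0.92), GstD7 (-0.85), Mcm2 (-0.80), mei-9 (-0.77), mRpS33 (-0.75), mRpS2 (-0.74), Obp22a (-0.70), Drsl1 (-0.68), Obp57b (-0.64), Cpr72Eb (-0.61), MED16 (-0.56), Obp50e (-0.56), Gclc (-0.54), MED10 (-0.46), Mcm3 (-0.40), EbpII (-0.39) and Taf10 (-0.37). Higher were CG15263 (1.46), CG9377 (1.28), GstT4 (1.26), Drak (1.25), Gk2 (1.13), mus81 (0.59), inaE (0.55) and Rdl (0.40).

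The responses of 14 lists differed by camera at the preset correlation and of 0 lists with an estimated one. Their median differences were -0.89 for the p53 list, -0.84 for antioxidant, -0.80 for fat body, -0.55 for heat shock, -0.42 for antimicrobial, -0.39 for ejaculatory bulb, -0.31 for accessory gland, -0.20 for cell cycle, -0.14 for DNA repair, -0.14 for odorant-binding, -0.13 for transcription, -0.12 for mitochondrial ribosomal, 0.0940 for cytosolic ribosomal and 0.10 for oxidative phosphorylation.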

How the results depend on the processing

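The alternatives combined with quantile normalization, the spike-in batch block and the 3' minus 5' covariate were chosen after the data were seen; the rest were fixed before. Where no reason is named below, the cause was not tested. Array signal over background limits weakly expressed genes, whose changes are compressed, and no detection calls were used here. Settings with a pseudocount were not run, because the values are already logarithms. Counts are given in the order Dsup lines against control untreated, the same at 1000 Gy, radiation in control flies, radiation in Dsup lines, and interaction.

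The deposited counts of 16742, 11606, 9297, 14489 and 4298 became 2003, 2258, 6384, 3999 and 1704 after quantile normalization, which by construction removes the offset between groups. Median centring moved 4 of them by over 1.5 times, to 3171, 4232, 3832 (radiation in Dsup lines) and 1479 (interaction), and ribosomal centring to 2393, 3862, 3053 and 1085; for radiation in control flies the 2 settings gave 6695 and 6552. An adjusted p below 0.01 left 1726 in the interaction, and a 2-fold minimum left 861, 450, 1061, 608 and 325. The level filter, which tests fewer probe sets, gave 10269 for untreated flies, 8544 for radiation in Dsup lines and 1036 for the interaction, and the mean of a gene's probe sets, with fewer features, 10873, 9402 and 2096.

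After quantile normalization the level filter gave 323, 477, 4054, 1918 and 137. The mean of a gene's probe sets gave 940, 1062, 2326 (radiation in Dsup lines) and 644 (interaction). Array weights gave 1272 for untreated flies, 6685 for irradiated flies and 2896 for the interaction, and only the groups compared gave 506 and 3573 for untreated and irradiated flies. The 3' minus 5' covariate gave 1686, 2006 and 956 for radiation in control flies, in Dsup lines and the interaction. The batch block moved no count by over 1.5 times (2160, 2036, 6941, 4507 and 2045), except that with irradiated control 3 put in the first batch it gave 1397 for irradiated flies. The Dsup line block gave 2026, 2379, 6432, 4027 and 1769. It changed the calls printed beside the results and no other named call.

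With each array left out in turn, the deposited counts ranged over 16140 to 16771, 9870 to 11879, 7507 to 9479, 13857 to 14690 and 2690 to 4598. After quantile normalization they ranged over 1386 to 2071, 1055 to 2623, 4616 to 6625, 3051 to 4293 and 866 to 1887. Without irradiated control 1, 2 or 3 in turn, irradiated flies gave 1106, 1055 and 1237 and the interaction 886, 866 and 959, with fewer arrays in an arm of 3. Lists called ranged over 59 to 67 as deposited and, after quantile normalization, 6 to 9, 4 to 9, 13 to 16, 5 to 7 and 11 to 15. On deposited values the correlation of the radiation responses ranged over 0.638 to 0.708 and that of the Dsup differences over 0.205 to 0.256.

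With an estimated correlation camera called 2 lists as deposited, against 64, and 0 in each comparison after quantile normalization, against 7, 6, 15, 6 and 14. Fry called 124 as deposited and 5 in the interaction after quantile normalization. The level filter moved the correlation of radiation responses from 0.694 to 0.805, and that of the Dsup differences went from 0.241 to 0.144 with the filter and 0.133 after quantile normalization.

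For 240 results of 164 named genes, 6861 values under other settings were 6274 times the same call, 476 times weaker, 100 times stronger and 11 times reversed. Besides the fits without 1 array, the settings with the most losses were the 3' minus 5' covariate (56), the level filter (35), only the groups compared (27) and array weights (23). Signs reversed on deposited values between untreated genotypes for cnc (-0.39), mRpS33 (-0.0900), mRpS2 (-0.20), mRpL12 (-0.33), EbpIII (-0.17), Mtp (-0.18), Obp57c (-0.24) and Obp22a (-0.18), between irradiated genotypes for Dp (-0.0426), and for radiation in Dsup lines for Cyt-c1L (0.11). The mean of the probe sets of cnc reversed too (-0.00727).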

Other observations

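Levels of the genes that mark the responses differed between lines. The mean over 18 members of the p53, antioxidant and heat shock lists called in the interaction, relative to untreated controls, was 2.23, 2.31 and 2.17 in irradiated controls 1 to 3, and 1.77, 0.71, 0.98 and 1.12 in irradiated Dsup lines 1 to 4. In untreated lines 1 to 4 it was 0.30, 0.08, 0.78 and 0.23. These members were picked by the interaction itself, so their separation of the groups is no independent test.

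The antennal genes were low in irradiated arrays of both genotypes, least so in irradiated Dsup line 3. The mean of the 11 genes chosen after their values were seen was -2.50, -3.10 and -3.21 in irradiated controls 1 to 3 and -2.75, -3.09, -1.61 and -3.18 in irradiated Dsup lines 1 to 4. All 11 were called lower in irradiated control flies, with a median of -3.31, and 10 in Dsup lines, with a median of -2.41. Untreated Dsup line 3 (-2.18) lowers the untreated mean of the lines. Obp84a of the second set fell by 1.70 in Dsup lines.

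Relative to their group means, arrays with the same line number were mostly no closer than others. By these deviations, line 2 alone of the 4 lines had its irradiated array correlate best with its own untreated array. Across all values, untreated line 3 was closest to irradiated line 3 (r = 0.991). After quantile normalization the 8 groupings of the 8 Dsup arrays that part every line's pair called at most 18 probe sets besides the real 3999.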
